A study of Mus musculus with 15 samples.

How the data were processed

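RNA sequencing libraries from total bone marrow of leukemic mice were analysed as 15 samples in 5 groups of 3, taken from the sample labels: 36S untreated, 36N untreated, KD untreated, 36S with TMZ and 36N with TMZ. Per the labels, RNA came from bone marrow cells of mice that had received leukemic cells after irradiation (7 and 3 Gy at first transplantation, 3 Gy at the serial ones), and a poly(A) selection module was used for library preparation in all samples. The deposited values are a normalized signal per gene, that is, gene counts that the authors had divided by library-specific factors before deposit. Per the submitters' processing notes the tools were Salmon and DESeq2 and the genome build was mm10, without versions or roles, and further steps are not given in the sources used here.

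The deposited tables numbered 4: untreated 36N and 36S (18075 genes), untreated KD and 36S (18075 genes), 36N with and without TMZ (17775 genes) and 36N and 36S with TMZ (19035 genes). The 36S values in the first and second tables were identical (largest difference 0), so these untreated libraries had been normalized together, while the other tables had been normalized separately and values were tested within a table. Column totals ranged from 11.27 to 24.26 in units of 1e6. Whole reads could not be recovered, since after undoing the best scale factor only 13.5 to 44.8% of low values came out whole within a tolerance of 0.1, so the read depth behind a value is unknown and no counting intervals are given. Gene symbols were matched to the GENCODE M21 annotation of mm10 for coordinates (17785, 17785, 17481 and 18683 symbols found), and no strand information was stated, so overlapping and antisense genes and near-identical copies share reads in an unknown way.

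Values were analysed as log2(normalized count + 1). Genes with a value of at least 10 in at least 3 libraries of a table were tested with limma-trend (limma 3.58.1 in R 4.3.3) on the libraries of the 2 groups compared, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were 36N against 36S untreated, KD against 36S untreated, TMZ against untreated within 36N, 36N against 36S with TMZ, the interaction of genotype and TMZ over 12324 genes with an intercept for each table and gene, and the overlap of the 36N and KD calls. KD against 36N was added after the tables were seen. TMZ within 36S was not tested because no table used here holds both groups. The shared 36S controls were handled with 100 simulations of unchanged groups.

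Pathway and cell type lists, 36 in all, were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. With an estimated correlation camera called 0 lists in every comparison, with lowest adjusted p-values from 0.41 to 0.79. For TMZ in 36N the lowest was 0.68, although the mast cell list had a median log2 fold change of 9.56. A missing call of this version therefore cannot tell a changed list from an unchanged one. Its p-values are given below as a limit only. Camera with the preset correlation assumes little co-regulation within a list, and its p-values are the smaller ones. Fry asks whether the genes of a list move, on balance, one way, and compares the list with no other genes. It called 0 lists for 36N against 36S, 11 for KD against 36S, 22 for TMZ in 36N, 0 for 36N against 36S with TMZ and 1 for KD against 36N.

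Genes named in the text followed a rule, and a few genes that it takes are not reported here. Gfi1, Mgmt, Brca1, Trp53, Cdkn1a, Mdm2, Myc, Hoxa9, Meis1 and Irf8 were named whatever their values. In each comparison the 10 largest increases and 10 largest decreases were named among genes with an adjusted p under 0.05, a mean of at least 50 in one group and groups that did not overlap. Unnamed gene models and pseudogenes were passed over, and where fewer than 5 genes passed, the 5 lowest p-values were named as not passing. For each list called, up to 4 members with the largest change past the threshold were named, or the 2 with the lowest p where none passed, and for the interaction the 10 with the lowest adjusted p. The groups, tests, gene lists, this rule and most alternatives were fixed before the data were examined. Other members of the lists and marker genes named beside them, among them Elane, Mpo, S100a8 and Ddx3y, the repair and GFI1-repressed genes that passed singly, and the genes under other observations were chosen after their values were seen.

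Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, equal totals, quantile normalization, fits without the trend or with a robust one, library weights, and each library left out in turn. A block by the library number in the titles was tried for TMZ within 36N. The check of this pairing gave correlations of 0.019, 0.037 and 0.086 between the deviations of same-numbered libraries, so the numbers were not taken to pair them. Alternatives chosen after seeing the data were a joint model of the 9 untreated libraries, a block of the TMZ library pairs that resemble each other, and leaving out libraries in the overlap.

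The fits were tested on simulated data with known changes drawn from the means and spreads of the real genes. For 36N against 36S, 50.9, 81.2 and 93.7% of genes changed 2-, 4- and 8-fold were recovered among 13065 genes, for KD against 36S 42.4, 80 and 90.6% among 13029, and for TMZ in 36N 33.9, 65.7 and 83.6% among 13729. The shares were, for 36N against 36S with TMZ 20.9, 67.7 and 79% among 14207, for KD against 36N 30.6, 82.5 and 92.8% among 13070 and for the interaction 21.2, 69.2 and 92.3% among 12268. Of genes changed 4-fold in both 36N and KD, 80.5% were shared calls among 12813 genes. Array weights used statmod 1.5.0, and further computation and plotting used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.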

Results

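Gene expression was measured by RNA sequencing in total bone marrow cells of leukemic C57BL/6 mice. The leukemias came from lineage-depleted bone marrow cells that carried the MLL-AF9 fusion oncogene on a retrovirus and had been passed serially through mice, and the marrow of the quaternary recipients was sequenced. The donors differed at the Gfi1 locus, which encodes a zinc finger repressor of transcription that acts in blood stem cells and in the choice between granulocytes and monocytes. Group 36S carried the human GFI1 gene at the mouse locus, group 36N carried the 36N variant of the human gene, and group KD expressed it at 10 to 20% of the usual level. There were 15 libraries in 5 groups of 3. Untreated groups were 36S (libraries 1 to 3), 36N (4 to 6) and KD (7 to 9). The other groups were 36S and 36N cells exposed to temozolomide (TMZ) at 50 µg/ml for 20 h before RNA isolation (36S TMZ 1 to 3 and 36N TMZ 4 to 6). TMZ is an alkylating drug that methylates DNA. The values were normalized counts in 4 tables. In units of 1e6, column totals lay between 11.27 and 11.93 for untreated 36N and 36S and between 11.27 and 13.03 for untreated KD and 36S. They lay between 15.69 and 18.29 for 36N with and without TMZ and between 22.25 and 24.26 for the TMZ libraries. Read depth before normalization is unknown. Values below are mean ± SD of normalized counts over 3 libraries, with the tested group first, and log2 fold changes are on the log2(value + 1) scale, which understates changes of genes near 0. P-values measure the spread between these samples, and whether the 3 mice of a group shared 1 primary leukemia is not stated in the labels. In the sample titles the number after MLL_AF9 runs from 1 to 3 for 36S and is 1 for all 36N and KD libraries. Its meaning is not given, so the p-values cannot be taken to cover the spread between leukemias.

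Gfi1 itself (mm10 chromosome 5, 107716657 to 107726036) was analysed in the table of 36N cells with and without TMZ, where it stood at 594 ± 115 with TMZ against 479 ± 102 without (log2 fold change 0.32, SE 0.21, adjusted p = 0.22). The modified alleles carry the human gene, so reads assigned to the mouse gene do not check the genotype labels, and the level of GFI1 in the 36S, 36N and KD groups was not analysed here.

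The first comparison asked which genes differ in the untreated marrow of MLL-AF9 leukemia when the 36N form replaces 36S. Of 8 genes of antigen presentation by MHC class II, 3 rose in 36N, and of 20 genes of cholesterol synthesis, 2 fell. Both lists had adjusted p = 0.79 with an estimated correlation. H2-Ab1, a chain of the class II molecule, rose from 97.0 ± 13.3 to 202 ± 23.8 normalized counts (log2 fold change 1.05, adjusted p = 0.017), and Idi1, an enzyme of the mevalonate pathway, fell from 408 ± 57.3 to 207 ± 48.1 (log2 fold change -0.99, adjusted p = 0.025). Irf8, a transcription factor of the monocyte and dendritic lineages (chromosome 8, 120736358 to 120756694), stood at 5009 ± 97.3 in 36N against 2965 ± 401 in 36S, which is 1.70-fold higher (log2 fold change 0.77, SE 0.12, adjusted p = 0.0084). Elane and Mpo, which encode neutrophil elastase and myeloperoxidase of the primary granules, fell by 1.25 and 1.48 on the log2 scale (adjusted p = 0.0087 and 0.036). Mpo spread widely within 36S, at 77510, 51640 and 26500 in libraries 1 to 3.

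Among 13137 genes tested with limma-trend, 335 were higher and 264 lower in 36N, and 182 and 181 of these changed at least 2-fold. Unadjusted p-values under 0.05 numbered 2679, against 657 for a test without effects. The 3 values of one group all lay above the 3 of the other for 26.9% of genes, where chance gives 10%. The largest increases among well-expressed named genes were in Vill (villin-like; chromosome 9, 119052778 to 119071525), at 1274 ± 207 against 20.9 ± 29.2 (log2 fold change 6.97, SE 0.90, adjusted p = 0.0040). They were followed by Arap2 (515 ± 202 against 18.5 ± 9.65), Rnase2a (51.6 against 2.99), Pla2g7 (106 against 11.2) and Camk2b. Further increases were in Vmn2r96 (493 against 65.0), Stfa3, Prox1 and Stfa2. The largest decreases were in Rnf17 (1.24 ± 2.16 against 97.2 ± 11.6), Ces1d (4.25 against 118), Scml2, Rgl3 and Hpse2 (18.5 against 339). Others were in Xlr, a lymphoid-regulated gene on the X chromosome (76.1 ± 81.9 against 1075 ± 131), Fam3b, Zfp575 (15.1 against 307), Sdk1 and Dip2c. These decreases had log2 fold changes from -5.86 to -4.04. Without 36S library 2 the calls fell to 188, and without 36N library 5 to 276. Leaving out 36S library 1, 36N library 4 or 36N library 6 gave 374, 362 and 361.

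Camera with its preset correlation called 8 of 34 gene lists in 36N, and 0 were called with an estimated correlation or by fry. Of 8 MHC class II genes tested, 3 rose and 0 fell, or 4 when adjusted over the list alone (median log2 fold change 0.66), with H2-Eb1 at 1.74 and H2-DMb2 at 1.10 beside H2-Ab1. This list had a camera adjusted p of 1.9e-04, and adjusted p = 0.79 with an estimated correlation. Of 20 cholesterol synthesis genes, 2 fell, Idi1 and the sterol carrier gene Stard4 (149 ± 34.7 against 274 ± 32.4), or 4 when adjusted over the list alone (median -0.47, adjusted p = 4.9e-06, and adjusted p = 0.79 with an estimated correlation). All 29 genes of G2/M and mitosis had negative fold changes with a median of -0.36 (adjusted p = 3.7e-07, and adjusted p = 0.79 with an estimated correlation). None of them passed over all genes and 4 fell when adjusted over the list alone, and the lowest p-values belonged to the mitotic kinesin Kif11 (-0.56, adjusted p = 0.051) and Prc1 (-0.45). Of 21 glycolysis genes, 1 fell, hexokinase Hk1 (1414 ± 174 against 2314 ± 81.3, log2 fold change -0.72), or 7 when adjusted over the list alone (median -0.30, adjusted p = 1.9e-04, and adjusted p = 0.79 with an estimated correlation).

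Of 16 genes of the integrated stress response and unfolded proteins, 2 fell in 36N, or 6 when adjusted over the list alone (median -0.27, adjusted p = 0.019, and adjusted p = 0.79 with an estimated correlation). They were Asns, which encodes asparagine synthetase (70.5 ± 23 against 256 ± 74.8, log2 fold change -1.86), and Herpud1 (-0.61). Called lower as well were the MYC and nucleolar list (29 genes, median -0.27, adjusted p = 0.0016), the G1/S and DNA replication list (25 genes, median -0.21, adjusted p = 0.019) and the heat shock list (10 genes, median -0.28, adjusted p = 0.022). With an estimated correlation these lists had adjusted p = 0.79 to 0.81. They had 0 members past the threshold over all genes, and 0, 0 and 1 when adjusted over the list alone. Examples were Myc (2935 ± 353 against 4141 ± 566, log2 fold change -0.49, adjusted p = 0.081), Bop1 (-0.41), Mcm3 (-0.32), Cdc6 (-0.36), Hsph1 (-0.85, adjusted p = 0.073) and Dnaja1 (-0.42).

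None of the DNA repair lists, which bear on the response to an alkylating drug, was called between untreated 36N and 36S. Mgmt, whose protein removes the methyl group that TMZ puts on guanine, stood at 68.1 ± 21.2 against 81.9 ± 3.60 (log2 fold change -0.31, adjusted p = 0.55). None of 35 homologous recombination genes passed (list adjusted p = 0.065), with Brca1 at -0.15 (adjusted p = 0.71). The glycosylase gene Ogg1 fell by 1.58 as the only base excision member of 23 past the threshold (list adjusted p = 0.55). Polm fell by 0.83 as the only one of 12 in end joining (list adjusted p = 0.62), and Rev3l rose by 0.64 as the only one of 20 in the Fanconi anaemia list (list adjusted p = 0.065). Trp53 (log2 fold change -0.30, adjusted p = 0.22) and its targets Cdkn1a (-0.12) and Mdm2 (0.07) did not pass. Nor did Hoxa9 (0.02) or Meis1 (0.15), homeobox genes that MLL fusions switch on. Of 17 MLL-fusion target genes, 3 rose (Flt3 1.94, Mef2c 1.34 and Bcl2 0.80) and 2 fell (among them Hoxa5 -2.13), with a list adjusted p of 0.55. Of 17 genes that GFI1 is known to repress, 3 rose, namely Gfi1b (2.05), Id2 (1.09) and Irf8 (list adjusted p = 0.91).

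**Figure D1:**
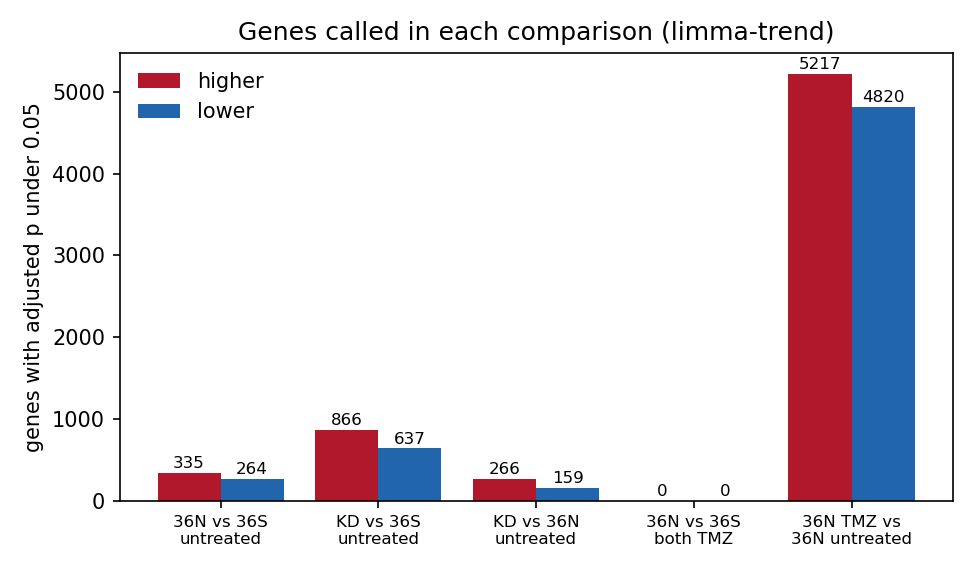
Numbers of genes with a limma-trend adjusted p under 0.05 in each comparison, drawn as bars from 0, with genes higher in the first named group in red and lower in blue. The bars read 335 and 264 for 36N against 36S, 866 and 637 for KD against 36S, 266 and 159 for KD against 36N, 0 and 0 for 36N against 36S under TMZ, and 5217 and 4820 for TMZ against untreated 36N.

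The comparison of KD with 36S asked which genes differ in leukemic marrow when GFI1 is expressed at a low level. Of 21 genes of monocytes and macrophages, 13 rose in KD, while 10 of 20 cholesterol synthesis genes and 9 of 35 homologous recombination genes fell. Each of these lists had adjusted p = 0.41 with an estimated correlation. Lyz2, which encodes lysozyme, stood at 40600 ± 11930 in KD against 10470 ± 936 in 36S (log2 fold change 1.92), and Irf8 was 2.25-fold higher at 6640 ± 32.5 against 2965 ± 401 (log2 fold change 1.17, SE 0.14, adjusted p = 0.0010). Lss, which encodes lanosterol synthase of the cholesterol pathway, fell from 153 ± 26 to 51.4 ± 13.9 (log2 fold change -1.58), and Xrcc3, a gene of homologous recombination, fell from 315 ± 29.7 to 167 ± 36.0 (log2 fold change -0.93). Markers of T and NK cells moved with these groups, Cd3e standing at 153 ± 96.9 against 15.9 ± 7.73. The immunoglobulin gene Igkc went the other way, at 547 ± 156 against 3558 ± 1607. The libraries are total bone marrow, and the share of leukemic cells in them was not analysed here. In all untreated comparisons, a difference in cell composition therefore cannot be separated from a change within leukemic cells. 36S library 1 stood apart in neutrophil genes, with S100a8 at 21822 against 2837 and 1365 in 36S libraries 2 and 3.

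Limma-trend called 866 genes higher and 637 lower of 13109 tested, 479 and 331 of them by at least 2-fold, and unadjusted p-values under 0.05 numbered 3469 where 655 would arise without effects. The groups did not overlap for 31.5% of genes, where chance gives 10%. The balance depended on scaling, since the deposited values gave 57.6% of calls higher and libraries brought to equal totals gave 39.4% (607 higher and 934 lower). The median over all genes moved from -0.01 to -0.13. Named increases were led by Rbm44 (372 ± 64.5 against 3.28 ± 2.99, log2 fold change 6.83) and the transcription factor genes Ikzf2 (494 ± 104 against 7.29) and Prdm16 (302 ± 12.1 against 3.63; chromosome 4, 154316125 to 154636873). Vill rose again (881 ± 109 against 20.9 ± 29.2). Next came Fam71b (89.0 against 0.667), Postn (228 ± 172 against 2.79), Sod3, Prg2 (721 ± 573 against 29.6 ± 20.7) and the chemokine gene Ccl5 (489 against 22.6). Decreases were led by Xlr (chromosome X, 53777118 to 53797706), at 3.35 ± 1.33 against 1075 ± 131 (log2 fold change -7.99, SE 0.29, adjusted p = 1.42e-06). They included Nlrp1a (1.54 against 197), Ces1d, Capn11, Rnf17 (0.79 against 97.2), Hif3a, Hpse2 (6.33 against 339), Mrgpra2b (3.88 against 185 ± 153), Mtus2 and the immunoglobulin gene Ighg2c (3.22 against 115 ± 92.1). Calls numbered 591 without 36S library 2, 976 without 36S library 3, 965 without KD library 7 and 611 without KD library 9.

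**Figure D2:**
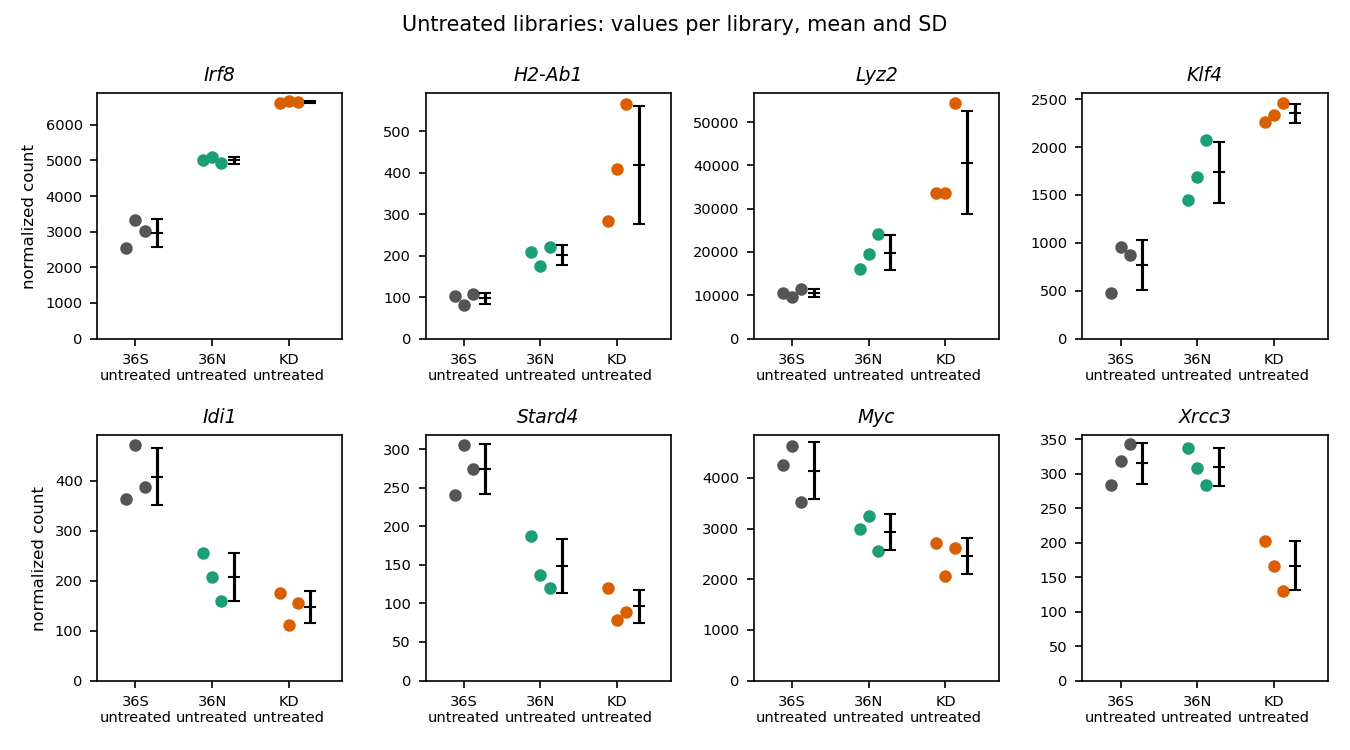
Normalized counts of 8 genes in the 9 untreated libraries, 1 dot per library, with mean and SD as black bars beside the dots, for 36S (grey), 36N (green) and KD (orange), and each vertical axis starting at 0. Irf8 reads 2965 ± 401, 5009 ± 97.3 and 6640 ± 32.5 in the 3 groups, and Stard4 and Xrcc3 have their lowest means in KD.

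Of 21 monocyte and macrophage genes, 13 rose and 0 fell in KD, or 14 when adjusted over the list alone (median log2 fold change 0.90, adjusted p = 1.03e-07, and adjusted p = 0.41 with an estimated correlation). They included the adhesion molecule gene Vcam1 (508 ± 144 against 131 ± 61.9), Apoe (2881 ± 564 against 804 ± 346) and Klf4 (2351 ± 101 against 766 ± 258). Of 8 MHC class II genes, 5 rose, or 7 when adjusted over the list alone (median 1.34, adjusted p = 1.17e-05, and adjusted p = 0.41 with an estimated correlation). H2-Eb1 rose by 2.95, H2-Aa by 2.22, H2-Ab1 by 2.05 and the invariant chain gene Cd74 by 1.74 (1960 ± 729 against 572 ± 140). Of 16 immediate early genes, 8 rose, or 11 when adjusted over the list alone (median 0.98, adjusted p = 2.1e-05, and adjusted p = 0.41 with an estimated correlation). Among them were Egr3 (1.86), Egr2 (1.78), Klf2 (943 ± 73.1 against 287 ± 34.3) and Fos (1.60). Of 11 T and NK cell genes, 5 rose, or 7 when adjusted over the list alone (median 1.93, adjusted p = 1.16e-04, and adjusted p = 0.56 with an estimated correlation). Cd3g rose by 3.24 and the granzyme genes Gzma and Gzmb by 3.17 and 2.95.

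Of 29 type I interferon genes, 8 rose and 2 fell in KD, or 12 and 2 when adjusted over the list alone (median 0.50, adjusted p = 0.0018, and adjusted p = 0.56 with an estimated correlation). Ifit3 (2.20), Oasl1 (2.13) and Mx1 (1.44) rose, and Oas2 fell by 1.59. Of 15 NF-kB and cytokine genes, 3 rose over all genes and over the list alone (Ccl2 2.30, Ccl3 0.92 and Nfkb1 0.76), with adjusted p = 0.015, and adjusted p = 0.41 with an estimated correlation. Of 7 mast cell, basophil and eosinophil genes, 4 rose and 1 fell, or 5 and 2 when adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.56 with an estimated correlation). The eosinophil granule gene Prg2 (4.47), the mast cell carboxypeptidase gene Cpa3 (1324 ± 117 against 215 ± 88.7) and Siglecf (1.66) rose, while Ms4a2, a chain of the IgE receptor, fell by 3.20. The nuclear oxidative phosphorylation list (73 genes, median 0.22, adjusted p = 0.0031) and the mitochondrially encoded list (13 genes, median 0.31, adjusted p = 0.026) were called higher with 0 members past either threshold, and had adjusted p = 0.79 and 0.73 with an estimated correlation. Sdhb stood at 0.47 (adjusted p = 0.068), Ndufc1 at 0.60, mt-Nd4 at 0.51 and mt-Nd6 at 0.49, and with equal totals the medians were 0.10 and 0.19.

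Of 35 homologous recombination genes, 9 fell and 0 rose in KD, or 16 and 1 when adjusted over the list alone (median -0.42, adjusted p = 6.9e-06, and adjusted p = 0.41 with an estimated correlation), and 17 fell with equal totals. Beside Xrcc3 these were Rad54b (117 ± 37.5 against 217 ± 25.5), the exonuclease gene Exo1 (210 ± 53.7 against 385 ± 66.6), Palb2 (178 ± 18.2 against 304 ± 23), Rad51ap1, Slx4, Rad50, Brip1 and Mre11a. Brca1 (371 ± 113, log2 fold change -0.56, adjusted p = 0.18) did not pass. Of 20 Fanconi anaemia genes, 4 fell, or 6 when adjusted over the list alone (median -0.44, adjusted p = 7.0e-04, and adjusted p = 0.41 with an estimated correlation). They were Faap100 (-0.83), Faap24 (-0.67), Slx4 (-0.63) and Brip1 (-0.54). Of 21 checkpoint genes, 3 fell, or 5 when adjusted over the list alone (adjusted p = 0.0079, and adjusted p = 0.49 with an estimated correlation). Those called were the kinase gene Wee1 (-0.78), Clspn (-0.67) and Cdc25a (-0.58). Of 19 mismatch repair genes, 2 fell over all genes and over the list alone, among them Exo1, with adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation. Mgmt stood at 56.2 ± 11.5 against 81.9 ± 3.60 (log2 fold change -0.55, adjusted p = 0.19). The other repair lists were not called: of 23 base excision genes 3 fell and 1 rose (list adjusted p = 0.12), of 12 end joining genes 2 fell and 1 rose (0.27), and of 24 nucleotide excision genes 0 passed (0.77).

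Of 20 cholesterol synthesis genes, 10 fell in KD, or 15 when adjusted over the list alone (median -0.61, adjusted p = 1.03e-07, and adjusted p = 0.41 with an estimated correlation). Beside Lss, decreases included Stard4 (-1.52) and Idi1 (-1.48). Of 29 MYC and nucleolar genes, 4 fell, or 6 when adjusted over the list alone (median -0.38, adjusted p = 6.7e-05, and adjusted p = 0.56 with an estimated correlation). These were Myc itself (2462 ± 351 against 4141 ± 566, log2 fold change -0.75, adjusted p = 0.016), the folate carrier gene Slc19a1 (-0.72), Nop58 (-0.64) and Wdr43 (-0.58). Of 25 G1/S and replication genes, 3 fell, or 4 when adjusted over the list alone (median -0.36, adjusted p = 9.95e-05, and adjusted p = 0.56 with an estimated correlation). These were Tk1 (-0.63), Cdc6 (-0.62) and Cdc45 (-0.62). The G2/M list had a median of -0.28 with 0 of 29 members past either threshold (adjusted p = 0.0018, and adjusted p = 0.68 with an estimated correlation), Bub1b at -0.46 and Kif11 at -0.52. Cdkn1a, the p53 target that inhibits cyclin-dependent kinases, fell from 554 ± 40.9 to 346 ± 34.8 (log2 fold change -0.68, adjusted p = 0.016). Trp53 (-0.07), Mdm2 (-0.04), Hoxa9 (0.42, adjusted p = 0.081) and Meis1 (-0.35) did not pass. Of 16 GFI1-repressed genes, 5 rose (Gfi1b 2.73, Egr2, Irf8, Id2 1.14 and Csf1r 0.98) and Cdkn1a fell, with a list adjusted p of 0.28.

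**Figure D3:**
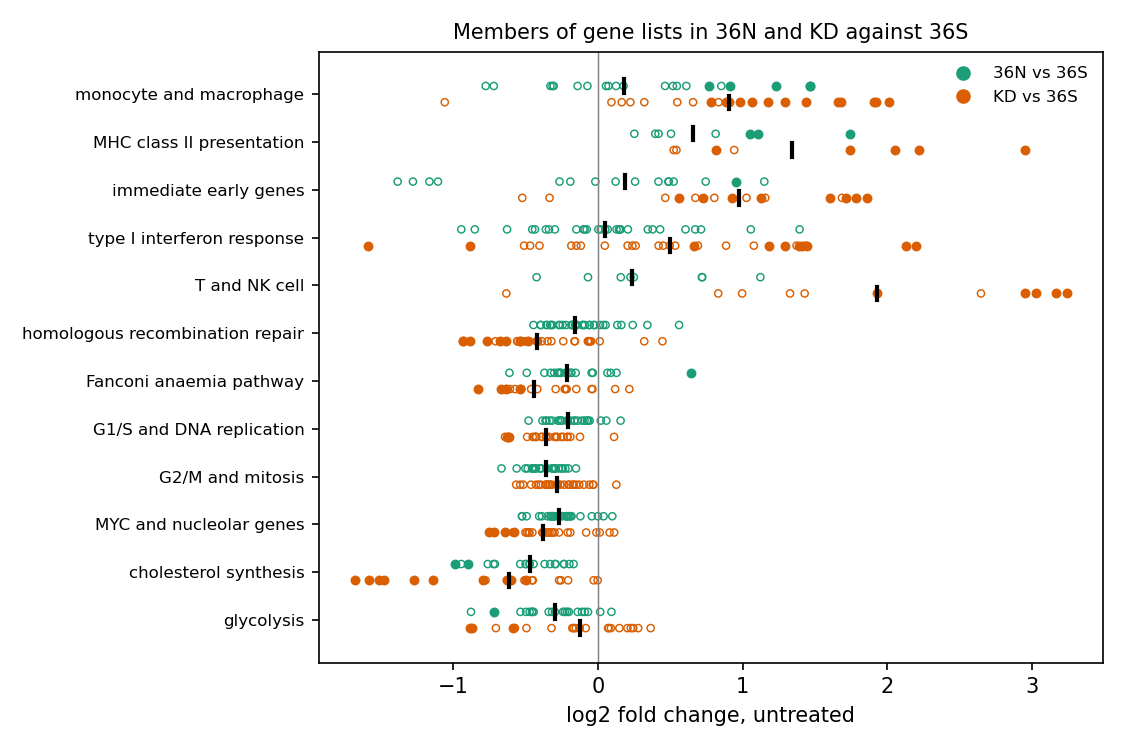
Log2 fold changes (x axis) of the members of 12 gene lists (y axis) in untreated 36N (green) and KD (orange) against 36S, 1 circle per gene, filled where the adjusted p was under 0.05, with black bars at the list medians. The monocyte list has a median of 0.90 in KD and the cholesterol synthesis list medians of -0.47 in 36N and -0.61 in KD.

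Many genes were called in both 36N and KD against 36S. Among 12870 genes tested in both, 201 were higher and 155 lower in both and 3 went opposite ways. Independent lists of these sizes would share 20.2 and 13.1. In 100 simulations of unchanged groups against the same 36S libraries, at most 1 gene was called per direction in a comparison. Their shared count of 0 was therefore all but certain beforehand and is no support for the overlap. Shared increases included Irf8, H2-Ab1, H2-Eb1, Vill and Arap2, and shared decreases Xlr, Rnf17, Ces1d, Hpse2, Idi1 and Stard4. Across these genes, which are not independent replicates, the log2 fold changes correlated at r = 0.64 (rho = 0.55), with 0.50 (rho = 0.46) in the simulations, and r was 0.354 to 0.540 when the 36S libraries were divided between the comparisons. The covariance was 0.258 against 0.0541 simulated. Without 36S library 2 the shared calls numbered 106, without 36S library 1 217, and without 36N library 4, 5 or 6 235, 200 and 237.

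KD and 36N were also compared directly, which was decided after the untreated libraries proved to have been normalized together. Of 6 mast cell, basophil and eosinophil genes, 4 rose in KD against 36N, as did 7 of 16 immediate early genes and 4 of 21 monocyte genes. These lists had adjusted p = 0.51 with an estimated correlation, and fry called 1 list. Cpa3 stood at 1324 ± 117 against 120 ± 156 (log2 fold change 4.38) and Apoe at 2881 ± 564 against 443 ± 45.4 (log2 fold change 2.68), whereas Irf8 (log2 fold change 0.41, adjusted p = 0.12) did not pass. Limma-trend called 266 genes higher and 159 lower of 13118 tested (62.6% higher, 49.7% with equal totals, when 176 were higher and 178 lower and the median over all genes moved to -0.13). Unadjusted p-values under 0.05 numbered 2491, and groups did not overlap for 22.6% of genes, where chance gives 10%. The largest increases were in Prdm16 (302 ± 12.1 against 0.597), Rbm44 (372 ± 64.5 against 1.17), Fam71b, the RNA-binding protein gene Msi1, Zfp575 (509 ± 210 against 15.1), Ikzf2, Postn, Scml2, Cpa3 and Raet1d. The largest decreases were in Nlrp1a (1.54 against 209), Galnt9, Vmn2r96 (13.1 against 493), Eps8l1, the neutrophil granule gene Camp (20.6 against 676), Mrgpra2b, Wfdc21, Ighg2b, Cldn1 and Xlr. Calls varied from 116 without KD library 9 to 1986 without KD library 8, with 209 and 171 without 36N library 4 or 5 and 237 without KD library 7.

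Of 16 immediate early genes, 7 rose in KD against 36N, or 10 when adjusted over the list alone (Egr2 2.89, Fosb 2.85, Jun 2.06 and Fos 1.35; adjusted p = 1.8e-07, and adjusted p = 0.51 with an estimated correlation). Of 21 monocyte genes, 4 rose, or 12 when adjusted over the list alone (Apoe, Cd14 2.38, Ly6c2 1.20 and Ccr2 0.89; adjusted p = 2.5e-06, and adjusted p = 0.51 with an estimated correlation). Of 6 mast cell, basophil and eosinophil genes, 4 rose, or 5 when adjusted over the list alone (Cpa3, Prg2 4.11, Siglecf 2.59 and Gata2 1.89; adjusted p = 1.3e-04, and adjusted p = 0.51 with an estimated correlation). Of 8 MHC class II genes, 2 rose (H2-Aa 1.41 and Cd74 1.32), or 4 when adjusted over the list alone (adjusted p = 0.0093, and adjusted p = 0.51 with an estimated correlation). The T and NK list (1 of 14 rose, Gzmb 2.10, or 7 when adjusted over the list alone; adjusted p = 7.9e-04) and the interferon list (1 of 29 rose, Zbp1 1.36, or 5 when adjusted over the list alone; adjusted p = 0.0019) were called higher as well. With an estimated correlation they had adjusted p = 0.53 and 0.67.

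Homologous recombination was the repair list with the lowest p in this comparison, with 1 of 35 genes called lower, Xrcc3 (-0.91), or 2 when adjusted over the list alone (median -0.32, adjusted p = 4.9e-04, and adjusted p = 0.51 with an estimated correlation). The checkpoint list (Timeless -0.45 and Clspn -0.57; adjusted p = 0.0093) and the Fanconi list (Rev3l -0.68 and Slx4 -0.37; adjusted p = 0.023) had 0 members past either threshold, and both had adjusted p = 0.51 with an estimated correlation. Of 25 G1/S genes, 2 fell over all genes and over the list alone (Cdc45 -0.77 and Tk1 -0.65; adjusted p = 0.030, and adjusted p = 0.70 with an estimated correlation). The stromal list of 7 genes was called lower (list adjusted p = 0.0050, and adjusted p = 0.51 with an estimated correlation). Its chemokine gene Cxcl12 fell by 1.70, just past the threshold in limma-trend (adjusted p = 0.0496). The nuclear oxidative phosphorylation list was called higher with 72 of 73 members positive and 0 passing (median 0.30, or 0.18 with equal totals; adjusted p = 1.8e-07, and adjusted p = 0.67 with an estimated correlation). The mitochondrially encoded list (median 0.42, mt-Nd2 0.59 and mt-Nd3 0.62; adjusted p = 0.0039) and the ribosomal protein list (median 0.14; adjusted p = 0.045) were called higher with 0 members rising. They had adjusted p = 0.67 and 0.84 with an estimated correlation, and after quantile normalization both medians were at or just below 0 (-0.0034 for the ribosomal list). Rplp0 fell (5961 ± 1338 against 12890 ± 1856).

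The next comparison asked which genes differ in 36N cells after exposure to TMZ. All 11 mast cell, basophil and eosinophil genes and all 20 cholesterol synthesis genes rose with TMZ, of 31 p53 targets 21 rose and 4 fell, and of 18 MLL-fusion targets 1 rose and 17 fell. Each of these lists had adjusted p = 0.68 with an estimated correlation. The mast cell carboxypeptidase gene Cpa3 stood at 73320 ± 27120 against 175 and was on average the gene ranked 13 by value in the TMZ libraries. Cdkn1a (chromosome 17, 29090976 to 29100727) rose 3.49-fold (2656 ± 177 against 760 ± 52.6, log2 fold change 1.80, SE 0.11, adjusted p = 9.2e-06) and the pro-apoptotic gene Bax from 228 ± 26.2 to 5405 ± 493 (log2 fold change 4.56). Hoxa9 fell from 2847 ± 1091 to 652 ± 167 (log2 fold change -2.07, adjusted p = 9.3e-04) and Flt3 from 2523 ± 856 to 20.3 ± 12.2. Replication-dependent histone genes moved with this group, 64 of 66 being lower with a median log2 fold change of -7.77.

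Limma-trend called 5217 genes higher and 4820 lower of 14390 tested, 3754 and 3430 of them by at least 2-fold, with 10409 unadjusted p-values under 0.05 and no overlap between groups for 74.5% of genes, where chance gives 10%. With equal totals 4681 were higher and 5322 lower, and the median over all genes moved from 0.06 to -0.09. All TMZ libraries of 36N stood on one side and all untreated ones on the other, and the labels give no batch, so the treatment and any difference in handling cannot be separated. The lowest values of the Y-linked genes Ddx3y and Eif2s3y were 0 and 1.8 among the 36N TMZ libraries, against 1064 and 674.6 among the untreated ones. Those of Kdm5d and Uty, also Y-linked, were not 0 but 75 and 74.7, against 1130 and 1429. A difference in the source of the cells therefore cannot be separated from the treatment either. The largest increases were in genes near 0 without TMZ. They were the basophil protease gene Prss34 (42300 ± 25780 against 0.975 ± 0.847), Cyp11a1 (16920 ± 4934, listed at 0 without TMZ) and the IgE receptor chain gene Fcer1a (14990 ± 7674, listed at 0 without TMZ). Next came Lama5 (32200 against 5.80), Tpsb2 (4095 ± 4116, listed at 0 without TMZ) and the platelet integrin gene Itga2b (36310 ± 11330 against 20.4 ± 15.3). Further increases were in the p53 target Perp (3267 ± 1430 against 1.10), Cma1 (4805 against 1.28), Ms4a2 (14000 against 12.7) and the IL-33 receptor gene Il1rl1 (15930 ± 4817 against 11.7 ± 3.11). The largest decreases were in Hpgd (2.08 ± 1.91 against 24530 ± 4907), the histone genes Hist2h2aa1 and Hist1h4h (listed at 0 with TMZ, 7657 ± 1076 and 6400 ± 619 without), and Hist2h3c2 (4.53 against 15320). Others were in Hist2h4, Hist1h1e (8.42 against 13830) and Hist1h4a, Col19a1 (listed at 0 with TMZ, 1491 ± 117 without) and the immunoglobulin genes Igkc (1.95 against 3373 ± 1025) and Igha.

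**Figure D4:**
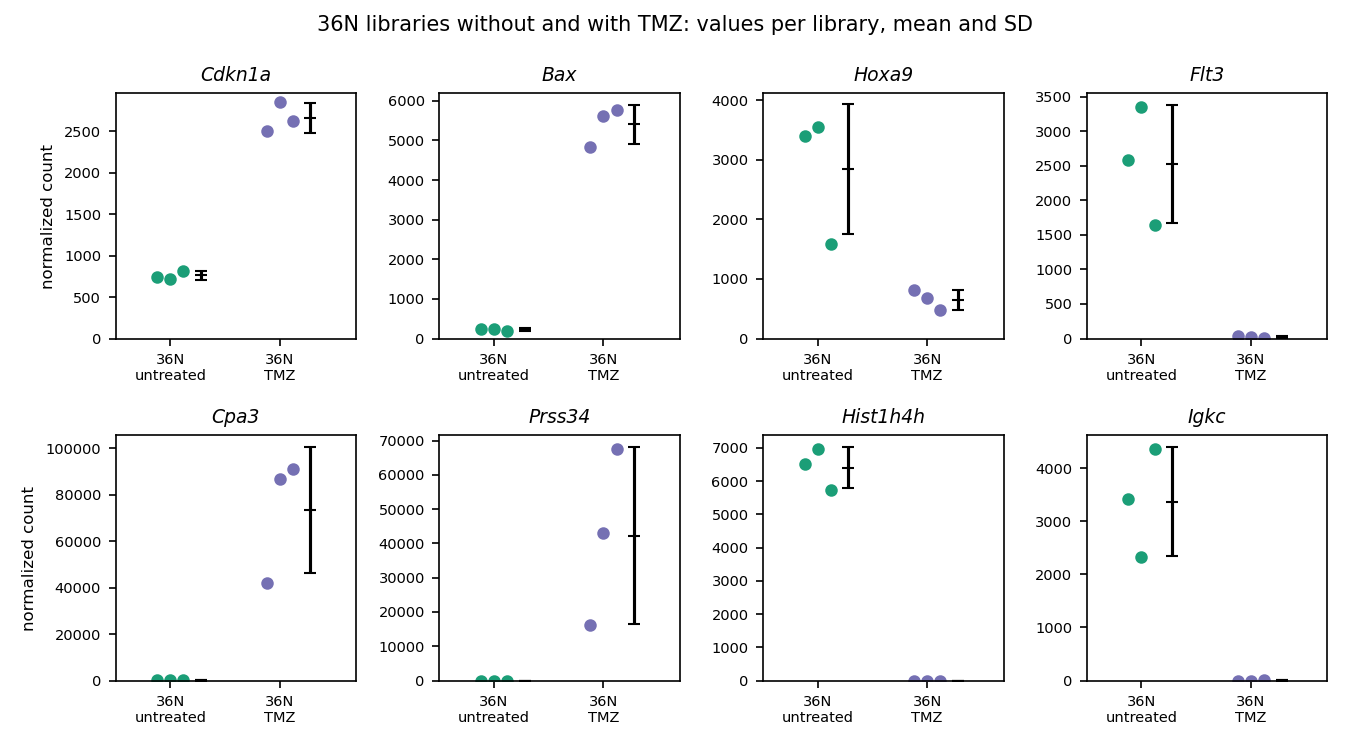
Normalized counts of 8 genes in 36N libraries without (green) and with TMZ (purple), 1 dot per library, with mean and SD as black bars beside the dots, and each vertical axis starting at 0. Cdkn1a reads 2656 ± 177 with TMZ against 760 ± 52.6 without, Cpa3 and Prss34 are near the axis without TMZ, and Hist1h4h and Igkc near the axis with it.

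All 11 mast cell, basophil and eosinophil genes rose with TMZ (median log2 fold change 9.56, adjusted p = 2.4e-04, and adjusted p = 0.68 with an estimated correlation). Of 10 megakaryocyte and platelet genes, 9 rose (median 4.55, adjusted p = 0.0034, and adjusted p = 0.68 with an estimated correlation). They included Pf4 (8.97), Ppbp (7.83) and Gp1bb (5.75). Of 8 B cell genes, 6 fell, including Ighm (146 ± 108 against 6675 ± 2498), Cd22 (-4.26) and Ms4a1 (-2.72), with adjusted p = 0.029, and adjusted p = 0.70 with an estimated correlation. Of 31 p53 targets, 21 rose and 4 fell (median 1.18, adjusted p = 0.0034, and adjusted p = 0.68 with an estimated correlation). Perp, Eda2r (5.46), Bax and Plk2 (4.18) rose most. Mdm2, which encodes the ubiquitin ligase of p53, rose from 1399 ± 56.9 to 1969 ± 275 (log2 fold change 0.48, adjusted p = 0.012), and Trp53 fell from 3385 ± 190 to 2138 ± 299 (log2 fold change -0.67, adjusted p = 0.0026). Of 18 MLL-fusion targets, 17 fell and 1 rose (median -2.51, adjusted p = 9.2e-05, and adjusted p = 0.68 with an estimated correlation). Flt3 (-7.03), Mef2c (-5.47), Hoxa3 (-5.17) and Hoxa10 (-4.88) fell most. Meis1 (-0.76, adjusted p = 0.019), Myc (-1.18, adjusted p = 0.011) and Irf8 (-3.82, adjusted p = 2.2e-04) fell too. Counts adjusted over the list alone were the same for all 8 lists called in this comparison.

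All 20 cholesterol synthesis genes rose with TMZ (median 1.87, adjusted p = 8.1e-06, and adjusted p = 0.68 with an estimated correlation). They were led by Lss (2410 ± 318 against 81.4 ± 45.5), Sqle (4.17) and Msmo1 (3.91). Of 18 stress response genes, 15 rose and 1 fell (median 1.76, adjusted p = 0.0020, and adjusted p = 0.68 with an estimated correlation). Increases included Vldlr (6.44), the amino acid transporter gene Slc3a2 (29940 ± 6463 against 481 ± 24.1), Trib3 (5.02) and the serine synthesis gene Phgdh (3.51). Of 21 glycolysis genes, 15 rose and 3 fell (median 1.26, adjusted p = 0.026, and adjusted p = 0.83 with an estimated correlation). Among the increases were Aldoc (3.02), the glucose transporter gene Slc2a1 (2333 ± 428 against 349 ± 62.7), Eno1 (2.34) and Slc16a3 (2.29). DNA repair lists were not called. Mgmt (81.2 ± 10.2 against 104 ± 32.2, log2 fold change -0.31, adjusted p = 0.39) and Brca1 (0.18) did not pass, and of 35 homologous recombination genes 11 rose and 12 fell (list adjusted p = 0.88). Alkbh2, a dioxygenase that reverses alkylation damage, rose from 26.7 ± 11.7 to 80.8 ± 10.4 (log2 fold change 1.65, adjusted p = 0.0055). Of all 14390 genes tested, 5217 rose and 4820 fell, so a single gene that passes is common in this comparison. As stated above, the treatment cannot be separated from handling or the source of the cells.

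The comparison of 36N with 36S under TMZ asked whether the variant changes expression in drug-exposed cells. No gene passed in limma-trend among 14246 tested, and 191 had an unadjusted p under 0.05 where 712 would arise without effects. The groups did not overlap for 4.76% of genes, where chance gives 10%. All named genes had an adjusted p of 0.9998. Cdkn1a was at 3927 ± 254 against 3322 ± 111 (log2 fold change 0.24), Mdm2 at 2782 ± 360 against 2416 ± 519, and Trp53 at 2594 ± 346 against 2576 ± 303. Of the repair genes, Mgmt was at 126 ± 15.8 against 149 ± 47.3 and Brca1 at 1330 ± 498 against 1279 ± 402. Myc was at 1780 ± 742 against 1945 ± 679, and Hoxa9 at 1009 ± 268 against 937 ± 260. Meis1 was at 1446 ± 395 against 1272 ± 212 and Irf8 at 839 ± 602 against 652 ± 512. The lowest p-values, none passing, were in Adam3 (2.76 against 36.4), Pcdhgc4 (105 ± 56.3 against 12.8), Bhlhe41 (67.0 against 16.6), Aqp3 (27.1 against 6.21) and Pkhd1l1 (23.1 against 94.4). Libraries of the 2 groups resembled each other in pairs. Their deviations from the group means correlated across genes at 0.392 between 36S TMZ 1 and 36N TMZ 4, at 0.447 between 2 and 5 and at 0.348 between 3 and 6. The other combinations, which centring on a mean of 3 pushes below 0, were at -0.124 or less. The Y-linked gene Ddx3y was at 0 in 36S TMZ 2 and 36N TMZ 5 and between 1646 and 2153 in the other 4 TMZ libraries. Kdm5d and Uty, also Y-linked, did not reach 0. Their lowest values were 229.5 and 165 among the 36S TMZ libraries and 169.9 and 139.6 among the 36N TMZ libraries. In the untreated libraries, 36S 2 and 36N 5 among them, Ddx3y lay between 551 and 701 in the separately normalized untreated tables.

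**Figure D5:**
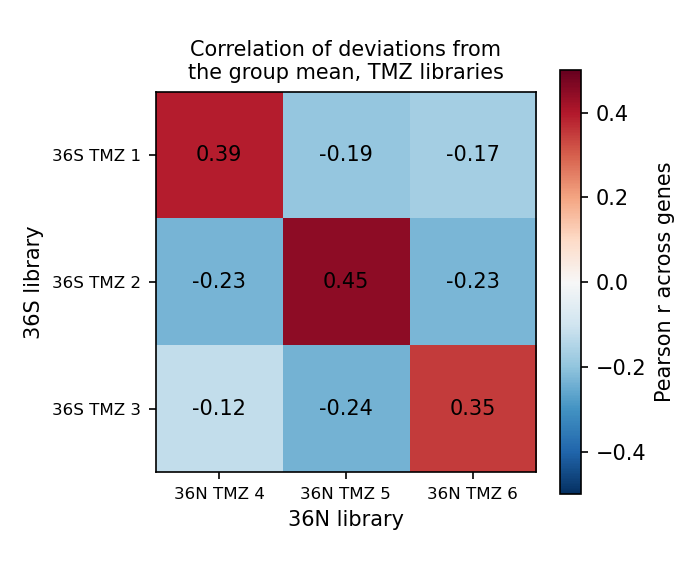
Pearson correlation across genes (color and number) of each 36S TMZ library's deviations from its group mean (y axis) with those of each 36N TMZ library (x axis). The diagonal reads 0.39, 0.45 and 0.35, and the other fields read -0.12 or less, which centring on a mean of 3 favours.

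Although 0 single genes passed under TMZ, camera with its preset correlation called 12 of 33 lists, 6 in each direction, all with 0 members past either threshold. Higher in 36N were interferon genes (median 0.35, adjusted p = 3.3e-04, Mx1 1.30 and Zbp1 0.78), mitochondrially encoded genes (adjusted p = 0.0020, mt-Nd3 0.33 and mt-Nd4 0.24), immediate early genes (adjusted p = 0.0066, Ier3 0.49 and Atf3 0.76) and NF-kB genes (adjusted p = 0.013, Traf1 0.85 and Ccl2 0.88). So were p53 targets (adjusted p = 0.032, Plk3 0.39 and Cdkn1a 0.24) and monocyte genes (adjusted p = 0.032, Fcgr1 0.59 and Mertk 0.79). Lower were erythroid genes (median -0.58, adjusted p = 1.07e-06, Rhd -1.28 and Rhag -0.95), ribosomal protein genes (74 of 75 negative, median -0.12, adjusted p = 0.0016, Rpl5 -0.32 and Rpl12 -0.38) and cholesterol synthesis genes (adjusted p = 0.0040, Dhcr7 -0.42 and Nsdhl -0.20). Also lower were MHC class II genes (adjusted p = 0.034, H2-Ab1 -0.29 and H2-DMa -0.26), G1/S genes (adjusted p = 0.043, Mcm4 -0.22 and Cdt1 -0.36) and neutrophil genes (adjusted p = 0.048, Ms4a3 -0.33, with Mmp8 in the other direction at 0.99). All of these had adjusted p = 0.68 to 0.75 with an estimated correlation, and fry called 0 lists. Without 36S TMZ library 3 the ribosomal list turned higher in 36N (adjusted p = 6.41e-12), and 3 lists were called in all. The neutrophil list turned to the other direction without 36S TMZ library 1 (adjusted p = 0.821) or 36N TMZ library 5 (0.234), and so did the G1/S list without 36N TMZ library 6 (0.740).

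The difference between 36N and 36S was itself compared between TMZ and untreated cells, taking the contrast within each table because the tables were normalized separately. Of 12324 genes, 41 passed, 29 with a higher and 12 with a lower 36N-36S difference under TMZ, and 861 unadjusted p-values were under 0.05. With the TMZ library pairs as a block, 110 passed, 72 higher and 38 lower. Dip2c had a log2 fold change of -4.04 without TMZ and 0.45 with it (difference 4.49, adjusted p = 9.7e-05). Fam3b had -4.32 and 0.02, Pard6b -3.35 and -0.21, and Zxdb -2.64 and 0.12. In the other direction Vill had 6.97 and 0.30 (difference -6.68, adjusted p = 0.030) and Arap2 4.79 and -0.66 (difference -5.44, adjusted p = 0.019). H2-Ab1 had a difference of -1.34 (adjusted p = 0.049). For Irf8 (-0.39, adjusted p = 0.96) and Idi1 (1.07, adjusted p = 0.16) a change with TMZ was not detected. The count was 18, 8 and 10 without untreated 36S library 1, 2 or 3, and 15, 18 and 27 without untreated 36N library 4, 5 or 6. It was 23, 17 and 34 without 36S TMZ library 1, 2 or 3, and 17, 14 and 23 without 36N TMZ library 4, 5 or 6.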

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

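Among the tests in this part, those of splits of the samples and of a GFI1 effect present in both treatments were chosen before their results were seen. Chosen only after were the tests of RNA selection, cell composition, TMZ itself, pairs of TMZ libraries, wrong labels, shared controls and 36S library 1. KD against 36N, the block of TMZ pairs and leaving out libraries in the overlap were also added after the data were seen. So were sorting the interaction draws by their untreated division and TMZ pairs, and the overlap draws by their reference.

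The difference between 36N and 36S differed between TMZ and untreated cells for 41 genes by the interaction test. The lowest adjusted p-values belonged to Dip2c (TMZ minus untreated difference 4.49 on the log2 scale), Gm10020 (-6.91), Zxdb (2.76), Gm49760 (-3.90), Fam3b (4.34), Ak3 (1.98), Zfp575 (4, untreated -4.22), Pard6b (3.14), Bhlhb9 (-3.87) and Pitpnm2 (-2.41). Gm10020 and Gm49760 are pseudogene models, whose reads can be shared with their parent genes. In the untreated cells these genes differed between 36N and 36S, and with TMZ all 10 had a log2 fold change between -0.41 and 0.45. Of 100 drawn splits of the samples, 8 gave as many genes as the real one and the highest of the others gave 487, a share that does not exclude chance for the division of the TMZ libraries. The 7 other draws as large all kept the real untreated division and regrouped only the TMZ libraries. Each of them placed both members of a resembling TMZ pair (1 and 4, 2 and 5 or 3 and 6) in the same group. Draws with the real untreated division that kept every such pair apart gave 37, 35 and 32 genes, against the real 41. The cause of these counts was not tested. The 89 draws that regrouped the untreated libraries gave at most 6.

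Other splits of the 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real splits called 599 genes (highest other 0) for 36N against 36S, 1503 (0) for KD against 36S, 10037 (0) for TMZ in 36N, 425 (0) for KD against 36N and 0 (2) for 36N against 36S with TMZ. The number of splits with as many genes was 1, 1, 1, 1 and 10. For gene lists the real splits called 8 (highest other 18), 17 (19), 8 (14), 14 (16) and 12 (13) in the same order, and 8, 2, 9, 2 and 4 of the 10 splits gave as many lists. For the genes called alike in 36N and KD, 1 of 100 splits, the real one, gave as many as 356, and the highest of the others gave 246. That draw kept the real groups and took KD as the shared reference. Of the other draws, 5 shared more than 100 genes, and all of these kept the 36S or the KD libraries together as the reference. A draw with 36S as reference and the 36N and KD libraries mixed shared 242. A large overlap thus also arose from mixed groups with an intact reference, so the draws cannot decide on a likeness of 36N and KD.

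The TMZ libraries of 36N differed from untreated ones by 10037 genes, a change that includes histone, mast cell, platelet and immunoglobulin genes. Different RNA selection at library preparation would go against the labels, which give poly(A) selection for all samples, and it stays open for the histone genes, because their median of -7.77 is the pattern itself and 0 other RNAs without a poly(A) tail were in the tested genes. It is argued against for the mast cell genes, which rose by 9.49 more than the ribosomal protein genes, both polyadenylated. Another cell composition of the TMZ libraries stays open as well, since the mast cell median of 9.56 prompted the idea and no separate measure was tested. Whether the p53 target median of 1.18 comes from TMZ itself cannot be told apart from these differences, because every TMZ library differed from every untreated one in them and the labels give no batch.

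The TMZ libraries of 36S and 36N were alike in pairs, and 0 genes separated the genotypes, with 191 unadjusted p-values under 0.05 in limma-trend. A shared source or day of each pair of libraries stays open, since the lowest correlation within pairs, 0.348, is the likeness itself and no separate measure was tested. With the pairs as a block limma-trend still called 0 genes. An exchange of labels between the 2 TMZ groups, or a single wrong library, is argued against as what hid a difference of the untreated size, because any other split called at most 2 genes and leaving a library out at most 1, against 188 or more untreated with a library left out. A smaller genotype effect, with or without a wrong label, stays open, as does why Ddx3y was 0 in the pair of 36S TMZ 2 and 36N TMZ 5 and present in every untreated library.

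The 36N and KD libraries differed from 36S in the same direction for 356 genes. Random spread of the shared 36S control libraries is argued against as the whole cause, because the covariance of the log2 fold changes was 0.258 and the highest of 100 simulated values 0.0603. The simulations gave all groups the same means, so they cannot speak to a 36S group that itself differs from both others. With KD as the shared reference, 36S and 36N shared 246 calls. 36S library 1, with its high neutrophil genes, may still contribute, since 52.8% of the shared calls remained without it (188 of 356), against 29.5% without 36S library 2 and 63.5% without 36S library 3. The bound first written was that over 50% should remain, but a stricter one, that the binomial interval exclude 50%, was adopted after the value was seen, which leaves this open. A GFI1 effect present in both treatments would need the shared calls to keep their sign under TMZ, and 63.6% did (208 of 327). For each other split, the larger of the shares keeping and changing sign was taken, which cannot lie below 50%. The highest of these was 67.3% and their median 53.5%, with the real share between them. The GFI1 effect therefore stays open, as does an untested difference between the primary leukemias.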

How the results depend on the processing

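The joint model of the 9 untreated libraries, the block of TMZ library pairs (also for gene lists and the interaction), the KD against 36N comparison and leaving out libraries in the overlap were chosen only after the data were seen; the other settings were planned. Gene counts of 36N against 36S (599) became 305 without the trend and 3304 with library weights, and ranged from 188 to 508 when a library was left out. KD against 36S (1503) gave 4289 with library weights and 591 to 2051 with a library left out, and KD against 36N (425) gave 203 without the trend, 3721 with library weights and 116 to 1986 with a library left out. The interaction count (41) was 27 with a filter of 50, 139 with library weights, 110 with the TMZ pairs as a block and 8 to 34 with a library left out. TMZ in 36N (10037) gave 8192 to 8901 with a library left out and 8531 to 11333 otherwise, and 36N against 36S with TMZ gave 0 to 1. Shared calls (356) became 629 at a threshold of 0.10 and 106 to 344 with a library left out. The joint model gave 584, 1724 and 536 genes for 36N against 36S, KD against 36S and KD against 36N. With the library number as a replicate block, genes changed by TMZ in 36N numbered 9985 (5189 higher and 4796 lower) with 9 gene lists, and the block of TMZ pairs gave 0 genes and 14 gene lists for 36N against 36S with TMZ, the 12 lists called without it among them in the same direction. The cause of these changes was not tested, except that a left-out library also means fewer samples.

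Gene lists called (8, 17, 8, 12 and 14 for 36N against 36S, KD against 36S, TMZ in 36N, 36N against 36S with TMZ and KD against 36N) fell to 0 in each comparison with an estimated inter-gene correlation and were 0, 11, 22, 0 and 1 with fry. As stated above, 0 calls with an estimated correlation cannot tell changed lists from unchanged ones. With a library left out, list calls ranged over 6 to 15, 14 to 17, 6 to 10, 3 to 12 and 10 to 16. Under TMZ, the neutrophil list reversed without 36S TMZ library 1 (adjusted p = 0.821) and without 36N TMZ library 5 (0.234), and its range was 7.66e-05 to 0.821. The list ribosomal proteins in 36N versus 36S, both TMZ, reversed without 36S TMZ library 3 (6.41e-12, range 6.41e-12 to 0.0141) and the G1/S list without 36N TMZ library 6 (0.740, range 1.84e-04 to 0.848). The correlation of 36N and KD fold changes moved to 0.354 to 0.540 with the 36S libraries divided. Each named gene was compared with its main fit in each setting. A gene past the threshold in both fits counted as kept if its direction held. A gene past it in neither counted as kept if its log2 fold change moved by less than its SE, whatever its sign. Of these pairs of gene and setting, 621 were kept for 36N against 36S (55 weaker, 15 stronger, 3 moved) and 1131 for KD against 36S (124 weaker, 23 stronger, 1 moved). The number was 829 for TMZ in 36N (3 weaker, 1 moved), 590 for 36N against 36S with TMZ (8 moved), 774 for KD against 36N (80 weaker, 24 stronger, 5 moved) and 201 for the interaction. TMZ in 36S was not run because no table used here holds both groups, nor was a model of all libraries on 1 scale, since the same library differed between tables by more than 1 factor. Read depth is unknown, so its limits were not assessed.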

Other observations

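The test of pseudogene models in this part was chosen only after the result was seen, and the genes below were chosen after their values were seen, while the test of the Gfi1 locus was planned.

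The stem and progenitor list was not called in untreated 36N (adjusted p = 0.14) or KD (0.82) against 36S, and single genes are given here. Kit, the receptor for stem cell factor, was lower in 36N (343 ± 176) and in KD (383 ± 124) than in 36S (1097 ± 178), with limma adjusted p = 0.023 and 0.0027. Gata2 was higher in KD (1086 ± 124 against 469 ± 65.6, adjusted p = 0.0013), with no detected change in 36N (302 ± 101, adjusted p = 0.14). Flt3 was higher in 36N (1710 ± 584 against 489 ± 284, adjusted p = 0.037), and Hlf fell in KD from 43.9 ± 17.5 to 4.16 ± 2.35 (adjusted p = 0.0055). Of the neutrophil granule genes, Elane fell in KD from 35190 ± 10470 to 10070 ± 1103 (adjusted p = 0.0016) and Mpo from 51880 ± 25500 to 14200 ± 1597 (adjusted p = 0.011). Lyz2, shared by monocytes and neutrophils, was higher in 36N (19880 ± 3999) as in KD. Neutrophil genes also separated 36S library 1 from libraries 2 and 3, Ltf standing at 5443 against 718 and 219.

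With TMZ in 36N, 6 of 17 erythroid genes rose and 1 fell, and this list was not called (adjusted p = 0.40). Of all 14390 genes tested, 5217 rose and 4820 fell. Single genes that rose were the transcription factor genes Gata1 (940 ± 199 against 16.5 ± 27.7, adjusted p = 0.0012), Tal1 (1951 ± 547 against 18.6 ± 24.5) and Klf1 (131 against 7.31). The globin gene Hba-a1 was at 40.1 ± 40.2 against 14.7 ± 12.6 (adjusted p = 0.21). The globin gene Hbb-bs was at 111.8 ± 45.1 against 9.83 ± 14.4, the lowest value with TMZ being 63.8 and the highest without it 26.4. Kit rose from 387 ± 198 to 13630 ± 3681 and Gata2 from 340 ± 113 to 13970 ± 3541. The genes that contribute to the MLL-AF9 fusion had very different levels as well. Kmt2a rose from 5782 ± 477 to 68080 ± 8663 (log2 fold change 3.55, adjusted p = 2.0e-06) and Mllt3 from 96.4 ± 28.8 to 15390 ± 3122 (log2 fold change 7.33, adjusted p = 7.5e-07). In the untreated libraries neither differed between genotypes by limma (adjusted p = 0.82 for Kmt2a and 0.38 for Mllt3 in 36N, 0.62 and 0.26 in KD). Reads of the retroviral fusion cannot be separated from those of the mouse genes in these values.

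Genomic sequence that came with the modified Gfi1 allele could have altered genes near the locus. Within 20 Mb of Gfi1, 47 of 283 genes (16.6%) were called in 36N or KD against 36S, and elsewhere 1614 of 12405 (13%), with an odds ratio of 1.33 (Fisher's exact test, two-sided, p = 0.0896), which did not reach the threshold and leaves the idea open.

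Reads shared between genes and their copies may contribute to the largest untreated changes. Of 92 calls with a log2 fold change of at least 4 in size, 27 (29.3%) were pseudogene models, against 4% of the genes tested. The calls were pooled over both untreated comparisons with the control group, so a gene called in both, such as Vill or Xlr, counted each time. The share among distinct genes is therefore not known.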
